A study of Mus musculus with 6 samples.

How the data were processed

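ChIP-seq for p53 was done in epidermal basal progenitor cells sorted by flow cytometry (high alpha-6 integrin and EpCAM positive) from 8-week-old mice of 2 genotypes, per the labels' protocols. Nutlin-3a was in the digestion medium at 25 µM, per the series' design text. Chromatin was prepared with a magnetic ChIP kit and libraries with a commercial DNA library kit, per the labels' protocols. The 6 libraries fall into WT and 3KR by their titles, 3 each. The submitters' processing notes name BWA and MACS2 without versions, and the mm10 build. The control library, the calling threshold, the read filters and the way libraries were combined are not given in the sources used here.

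The files analysed were 2 lists of summits, 1 per genotype, each assigned by the labels to the 3 libraries of its genotype. Every entry is a single base, 1668 in the WT list and 6753 in the 3KR list. The column of values was made by the authors with the peak caller and is read here as −log10 of the p-value or q-value of each peak, as MACS2 writes it. Which of the 2 it is cannot be read from the deposited lists. It ranged from 2.76 to 295 in WT (median 9.42) and from 2.53 to 275 in 3KR (median 10.1). Scores were used only within a list, to rank and filter summits and to compare shared with other regions, since the lists were called separately. Summit names in each list carry 1 run label. The WT label ends in the number 1 and the 3KR label contains Doxo. This disagrees with labels that describe combined libraries and Nutlin-3a, and it is open whether each list rests on all 3 libraries and whether Doxo names a compound given to 3KR cells only. Depth per library was not used here, so it is unknown how far the lists differ because of depth. More reads give more summits from the same binding, and a score grows with depth.

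Each summit was widened by 100 bp to either side, to windows of 201 bp, and overlapping windows of a list were merged (1667 and 6752 regions), keeping the summit with the highest score. Regions were shared if their windows had at least 1 bp in common, which means summits at most 200 bp apart. Coordinates are 1-based on mm10. Gene positions came from a RefSeq table of assembly GRCm38.p6, whose primary chromosomes are those of mm10. The table gives no strand and no exons, so the planned transcription start site was replaced by either annotated end of a gene, promoters by summits within 1 kb of a gene end, and exons and introns by gene body. A sequence of the genome was not used here, so the planned p53 motif comparison was not run. Peak widths were not used here, so fixed windows stand for the planned peak widths, and random placements were confined to the span of annotated or called positions of each chromosome in place of excluding assembly gaps. Summits on X, Y, mitochondrial and unplaced sequences entered the overlap. The comparisons of location and genes used assembled chromosomes only, leaving out 29 unplaced and 3 mitochondrial summits in WT and 62 and 6 in 3KR.

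Chance overlap came from 10000 random placements for WT (1000 for 3KR, for location and for each alternative), with one-sided p-values. Shares have 95% Wilson intervals and odds ratios 95% Woolf intervals, with 0.5 added to each cell where a cell was 0. Gene-end shares were compared with 2-sided Fisher's exact tests and scores with 2-sided permutation tests of medians (100000 resamples). A gene had a peak if a summit lay within 10 kb of either end, and 18 gene lists with 364 names, 361 of them in the table as protein-coding, were tested with one-sided Fisher's exact tests. The 36 tests of both genotypes shared a Benjamini-Hochberg adjustment at a threshold of 0.05. The background was 21887 protein-coding genes. The difference between genotypes used 2-sided Fisher's exact tests among genes with a peak in exactly 1 list. Neighbouring genes can share a summit, so genes are not independent, and adjusted p-values are then too small. Lists overlap: 13 of 24 apoptosis genes, 10 of 20 cell cycle genes, 7 of 26 metabolism genes, 6 of 20 DNA repair genes and 5 of 12 feedback regulators are also known targets.

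Gene lists, tests, and the rule for named genes were fixed before the data were examined. The rule takes every list gene with a WT summit (37 genes), up to 30 list genes of the 3KR list by rank, the genes nearest to the 10 highest scored regions of each list, and those nearest to the 5 highest scored regions of each class. It names 73 genes, of which 1 is not reported here. Alternatives varied the overlap rule, the list length, the score threshold, the chromosomes, the distance to genes, the gene assignment, the biotypes and the placement of random regions. The overlap and gene list steps were tested on simulated lists, made by moving the summits on assembled chromosomes to random positions. With 300 planted shared summits 301 were found, with none planted 2 were found, all 39 planted target genes were recovered, and 0 lists without planted genes were called. Planted summits lay well inside the distances of the rules, so their recovery checks only that the steps ran as written. Random positions lack the excess at gene ends of the real lists, so the 0 calls give no rate of false calls for these data. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.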

Results

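The binding of p53 to chromatin was measured by ChIP-seq in basal progenitor cells of mouse epidermis, the dividing cells of its innermost layer. Cells carried either wild-type p53 (WT) or the p53 form named 3KR. From general knowledge of this allele, 3KR is a p53 in which 3 lysines of the DNA-binding domain are replaced by arginine, so that they cannot be acetylated. The labels give only its name. There were 3 libraries of each genotype, 6 in all. The mice were 8 weeks old, and Nutlin-3a, a compound that keeps MDM2 from degrading p53, was present at 25 µM while the tissue was digested. The series sets out to find the genes bound by each form of p53. One combined list of peak summits per genotype was analysed, with 1668 summits for WT and 6753 for 3KR, 4.05 times as many. No list holds values of single libraries, so no spread between animals can be given, and the sequencing depth behind each list is unknown. Every p-value counts peaks or genes as they stand in these lists, and every interval covers counting error only. A caution applies to each comparison: the summit names carry a run label that for WT ends in the number 1 and for 3KR contains the word Doxo, although the labels describe combined libraries and Nutlin-3a. Whether Doxo names a compound, such as doxorubicin or doxycycline, that was given to 3KR cells only cannot be read from the labels.

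The first comparison asks how far the summits of the 2 lists lay at the same sites. Of 1667 WT regions, 884 had a 3KR summit within 200 bp, or 53.03% (95% Wilson interval 50.6 to 55.4). Of 6752 3KR regions, 881 were shared, or 13.05% (12.3 to 13.9), which left 783 WT-only and 5871 3KR-only regions. Shared summits lay close together, at a median distance of 22 bp (quartiles 9 and 50 bp), and 48.1% were within 20 bp of each other. Sites in both lists included a site at one end of Polh, which encodes the translesion DNA polymerase eta, and sites beside Krt5 and Krt14, which encode the keratins of basal cells. Random placement of the WT regions on their own chromosomes gave a mean of 5.05 shared regions and at most 13. The one-sided p from this permutation of positions was 1e-04, the smallest that 10000 placements can give. Random placement does not allow for background signal that both lists may share, so the overlap alone does not show binding of p53. When the 3KR list was shortened to the length of the WT list by score, 31.2% of WT regions were shared. With deposited single-base summits and no window, 1.08% coincided exactly.

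Sharing rose with the score that the authors' peak caller gave each summit, a −log10 p or q value that was compared only within a list. In the lowest decile of the WT list 30.5% of regions were shared (24.1 to 37.9), and in the highest decile 95.2% (90.8 to 97.6). In the 3KR list the share went from 4.14% (2.88 to 5.92) to 48.2% (44.5 to 52.0). Shared WT regions had a median score of 11.8, against 7.67 for WT-only regions. In the 3KR list these medians were 20.6 and 9.39. Both differences had a 2-sided permutation p of 1e-05, the smallest that 100000 resamples can give. A high score does not by itself mark a p53 site. On assembled chromosomes, 0 of 159 WT regions and 5 of 664 3KR regions of the highest decile lay within 10 kb of an end of a known target. Of WT regions, 24 of 29 on unplaced sequences, 13 of 14 on X and 10 of 10 on Y were shared, against 51.9% on chromosomes 1 to 19 and 1 of 3 on mitochondrial sequence.

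**Figure D1:**
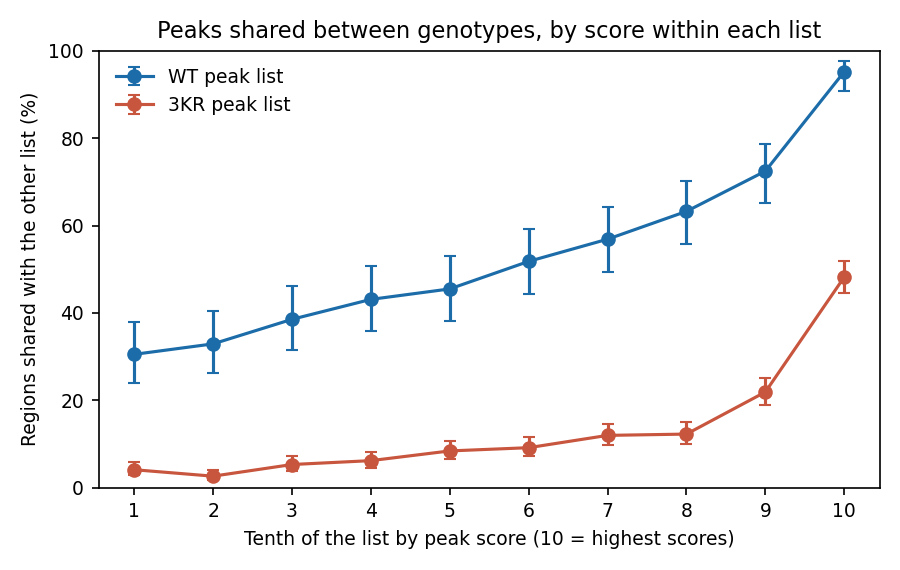
Percentage of merged peak regions shared with the other genotype's list (vertical axis) in each decile of a list ordered by peak score (horizontal axis), WT in blue and 3KR in red, with 95% Wilson intervals as bars. The WT share runs from 30.5% in the lowest decile to 95.2% in the highest, and the 3KR share from 4.14% to 48.2%.

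The highest scored sites were nearly the same in both lists, and most lay outside protein-coding genes. Of the 10 highest scored regions of each list, 8 were common to both, and all 10 of each list were shared sites. In WT the highest score, 295, belonged to a summit at position 103649179 of chromosome 6 (mm10), inside Chl1, a neural cell adhesion gene. Next came a summit at 3109991 on chromosome 12, 137 kb from Rab10, and one at 35305377 on chromosome 9, 29.4 kb from Rpusd4. The others of the WT list lay nearest to Wls, a carrier of Wnt proteins, at 0.874 kb, to Tmem196, B230307C23Rik, Cr2, Gm45871, Tcstv3 and Mrgprd. In the 3KR list the sites near Rpusd4, Rab10, Chl1, Wls and Tmem196 took the 5 highest places, with scores of 275, 253, 249, 241 and 230, and the 10 highest also held a site 12.0 kb from Gm14496 and one on an unplaced sequence. Only 1 of the 10 lay inside a protein-coding gene in either list.

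Among WT-only regions the highest scored were a second site near Chl1, 196 kb away at 103314651 on chromosome 6, and sites near Frmd4a, Gm42048, Zfp825 and Zfp326, with scores from 30.8 to 125. Among 3KR-only regions they were a site inside Smurf1, which encodes a ubiquitin ligase, at 144898638 on chromosome 5, and a site inside Ece1, which encodes an endothelin-converting enzyme, at 137879667 on chromosome 4. Sites 7.31 kb from Serpinh1, a collagen chaperone, 15.1 kb from Col1a1, a collagen chain, and 3.04 kb from Capn2 followed. These 5 scored between 115 and 144 and ranked 22 to 41 in the 3KR list.

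The second comparison asks where the sites lie relative to genes. Among regions on assembled chromosomes, 31.6% of 3KR-only regions (1840 of 5828, 30.4 to 32.8) lay within 1 kb of an end of a protein-coding gene. The share was 17.5% of shared regions (150 of 859, 15.1 to 20.1) and 6.96% of WT-only regions (54 of 776, 5.37 to 8.97). Random placement gave 3.13% to 3.17%, so the 3 classes stood 9.95, 5.56 and 2.22 times above chance in that order. Each exceeded all 1000 placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). WT-only regions were intergenic in 51.3% of cases (47.8 to 54.8), shared regions in 46.7% (43.4 to 50.03) and 3KR-only regions in 35.3% (34.1 to 36.6). Examples of 3KR-only sites at a gene end are those of Sdha, a mitochondrial respiratory enzyme, 15 bp away, of Psmb2, a proteasome subunit, 17 bp away, and of Cop1, an E3 ubiquitin ligase that can act on p53, 2 bp away.

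By 2-sided Fisher's exact tests, 3KR-only regions were at gene ends more often than WT-only regions (odds ratio 6.17, 95% interval 4.65 to 8.18, Benjamini-Hochberg adjusted p = 1.7e-56). Shared regions were at gene ends more often than WT-only regions (odds ratio 2.83, 2.04 to 3.93, Fisher's exact adjusted p = 7.1e-11) and less often than 3KR-only regions (odds ratio 0.459, 0.381 to 0.552, Fisher's exact adjusted p = 2.5e-18). With a 5 kb distance, with all gene biotypes, and without the highest score decile of both lists, the first odds ratio was 3.05, 3.49 and 3.35.

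**Figure D2:**
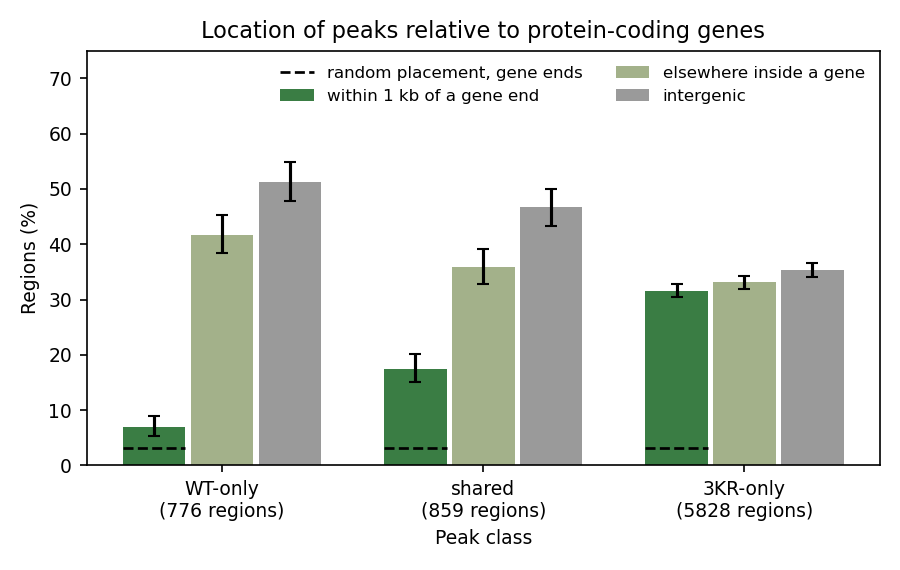
Percentage of peak regions (vertical axis) within 1 kb of an end of a protein-coding gene, elsewhere inside a gene, or intergenic, for WT-only, shared and 3KR-only regions (horizontal axis), with 95% Wilson intervals as bars and the random expectation for gene ends as dashed lines. The gene-end share is 6.96% for WT-only, 17.5% for shared and 31.6% for 3KR-only regions.

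The third comparison asks which genes lie beside the sites. In WT, 745 of 21887 protein-coding genes (3.40%) had a summit within 10 kb of either end, and in 3KR 4325 genes (19.8%). Of these, 570 genes had a summit in both lists, 175 in WT only and 3755 in 3KR only. Known p53 target genes were called in both genotypes. In WT 19 of 98 had a summit, against 3.33% of other genes (odds ratio 6.98, 4.21 to 11.6, one-sided Fisher's exact test, adjusted p = 2.6e-08). In 3KR 45 of 98 had one, against 19.6% of other genes (odds ratio 3.47, 2.33 to 5.17, Fisher's exact adjusted p = 7.3e-08). Theirs were not the highest odds ratios of the lists described below: basal epidermal genes and feedback regulators stood higher in WT (9.53 and 9.49), and housekeeping, AP-1 and cell cycle arrest genes in 3KR (4.07, 4.07 and 3.66). With the 3KR list shortened to the WT length, 11 of 98 targets had a 3KR summit (odds ratio 2.11, Fisher's exact adjusted p = 0.164), and the number of gene lists called for 3KR went from 8 to 0.

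The same summit served both genotypes at 12 known targets, namely Cgrrf1, Gtse1, Kcnn4, Orai3, Phlda3, Polh, Ppm1d, Rap2b, Rps27l, Serpinb5, Sfn and Susd6. Polh (chromosome 17, 46171355 to 46202641) had summits at 46202729 in WT and 46202723 in 3KR, 88 and 82 bp outside the gene, with rank 275 of 1667 and rank 52 of 6752. Serpinb5, which encodes the serpin maspin (chromosome 1, 106861175 to 106883348), had them at 106860978 and 106861012. Ppm1d encodes a phosphatase that switches p53 signalling off, and Phlda3 a repressor of Akt. Sfn encodes a 14-3-3 protein of the cell cycle checkpoint. Further targets, Mdm2, Perp and Stx6 among them, had summits in both lists at different positions. At Mdm2, the gene of the ligase that degrades p53 (chromosome 10, 117688875 to 117710758), the WT summit at 117710100 lay inside the gene, 658 bp from its end. It ranked 1595 of 1667. The higher of the 3KR summits, at 117717742, lay 6984 bp outside the gene and ranked 138 of 6752.

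Known targets with a summit only in WT were Bbc3, which encodes the apoptosis inducer PUMA, Ccng1, a cyclin gene, and Slc12a4, a cotransporter gene. The summit of Bbc3 was at 16308697 on chromosome 7, 299 bp inside the gene, and that of Ccng1 at 40755365 on chromosome 11, 56 bp outside. The WT summits of Bbc3, Ccng1 and Slc12a4 ranked 908, 1463 and 1462 of 1667. Low scored WT regions were seldom shared whatever their gene (30.5% in the lowest decile), so these ranks limit what a missing 3KR summit can mean. Another 29 targets had a summit only in 3KR. Among them were Cdkn1a, which encodes a cyclin-dependent kinase inhibitor that halts the cell cycle, Triap1 and Abhd4. The higher 3KR summit of Cdkn1a (chromosome 17, 29090979 to 29100722) was at 29095362, inside the gene and 4383 bp from an end. A WT summit stood 11907 bp outside Cdkn1a, at 29079072, beyond the 10 kb distance. Sesn1, also among the 29 and named after its values were seen, had a WT summit 26785 bp from its nearer end, inside the gene and shared with 3KR.

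**Figure D3:**
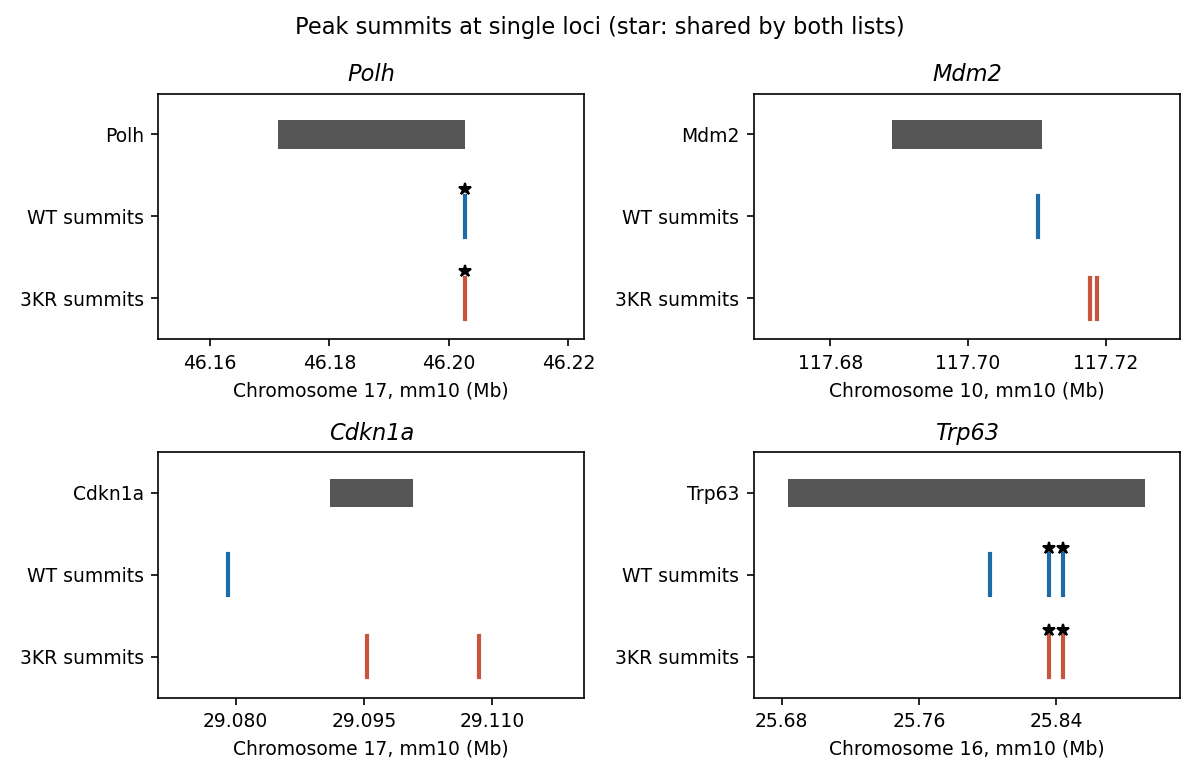
Maps of Polh, Mdm2, Cdkn1a and Trp63 with the gene as a grey bar, WT summits as blue marks and 3KR summits as red marks against the mm10 position in Mb, and stars on summits shared by both lists. Polh has 1 shared site, Trp63 has 2, and the summits at Mdm2 and Cdkn1a lie at different positions in the 2 lists.

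Among smaller p53 groups, feedback regulators of p53 had a summit at 3 of 12 genes in WT, Ccng1, Mdm2 and Ppm1d (odds ratio 9.49, 2.56 to 35.1, Fisher's exact adjusted p = 0.0275). All 3 are also known targets, so this call is not independent of theirs. Their WT summits ranked 1463, 1595 and 1323 of 1667. In 3KR 5 of 12 feedback regulators had a summit (2.90, 0.921 to 9.15, Fisher's exact adjusted p = 0.166), Cop1, Mdm2, Ppm1d, Trp53 and Trp53inp1, of which Trp53 and Trp53inp1 are named after their values were seen. Genes of metabolism and mTOR signalling had one at 4 of 26 in WT, Gamt, a creatine synthesis gene, Gpx1, a glutathione peroxidase gene, Aldh4a1, a proline breakdown gene, and Acad11 (odds ratio 5.18, 1.78 to 15.1, Fisher's exact adjusted p = 0.0347). The 3KR value was 7 of 26 (1.497, 0.629 to 3.56, Fisher's exact adjusted p = 0.436). Cell cycle arrest genes were called in 3KR, at 9 of 19 with Cdkn1a and Cdkn1b, another kinase inhibitor gene, among them (odds ratio 3.66, 1.49 to 9.01, Fisher's exact adjusted p = 0.0275). In WT they were Gtse1 and Sfn, 2 of 19 (adjusted p = 0.287, Fisher's exact test). At the 10 kb distance apoptosis genes passed the threshold in neither list (3 of 24 in WT, Fisher's exact adjusted p = 0.120, and 9 of 24 in 3KR, adjusted p = 0.0931), nor did DNA repair genes (1 of 20, adjusted p = 0.692, and 7 of 20, adjusted p = 0.185). Ferroptosis genes were called in 3KR (10 of 22, odds ratio 3.39, 1.46 to 7.85, Fisher's exact adjusted p = 0.0275), with Vkorc1l1 and Slc3a2 among them, and not in WT, where Tfrc and Slc3a2 had a summit (2 of 22, adjusted p = 0.325). Of the 7 alternatives run for each list, 2 ended the call for feedback regulators in WT. In the top 50% by score 0 of 12 genes remained (odds ratio 2.32), and with shared summits only 1 of 12 (3.99). The call for metabolism in WT ended under 3 alternatives, where the odds ratio stayed between 4.87 and 7.91 with fewer genes (2, 2 and 3 of 26). In 3KR, 4 ended the call for cell cycle arrest (odds ratio 1.95 to 3.005) and 3 for ferroptosis (1.87 to 3.53). Other alternatives added calls, all by Fisher's exact tests. Feedback regulators were called in 3KR at 50 kb (11 of 12, odds ratio 15.6, adjusted p = 0.00325), by nearest gene (7.61, adjusted p = 0.00209, Fisher's exact test) and with gene bodies, an alternative chosen after seeing the data (6.57, adjusted p = 0.00781). Cell cycle arrest genes were called in WT by nearest gene (5 of 19, odds ratio 5.84, Fisher's exact adjusted p = 0.00903). Apoptosis genes were called in WT within 1 kb (3 of 24, odds ratio 13.6, Fisher's exact adjusted p = 0.0142) and in 3KR at 50 kb (16 of 24, 2.84, adjusted p = 0.0262) and with gene bodies (11 of 24, 2.78, adjusted p = 0.0420). DNA repair genes were called in 3KR within 1 kb (7 of 20, odds ratio 4.53, Fisher's exact adjusted p = 0.0203).

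Genes of basal epidermal identity were beside sites of both lists. In WT 6 of 24 had a summit, Krt5, Krt14, the integrin genes Itgb4 and Itga3, Cdh3, the P-cadherin gene, and Egfr (odds ratio 9.53, 3.77 to 24.1, Fisher's exact adjusted p = 0.00146). In 3KR 11 of 24 had one (3.44, 1.54 to 7.69, Fisher's exact adjusted p = 0.0205), and 5 genes, Cdh3, Itga3, Itgb4, Krt14 and Krt5, shared the same summit. Krt5 (chromosome 15, 101707069 to 101712905) had it at 101713862 in WT and 101713920 in 3KR, 957 and 1015 bp outside the gene. Tfap2a, a transcription factor gene, was among those with a 3KR summit only. Within 1 kb of gene ends the calls were lost. There the WT odds ratio stayed near its 10 kb value, at 8.63 with 2 of 24 genes (Fisher's exact adjusted p = 0.113), while that of 3KR fell to 1.2005 with 3 of 24 (adjusted p = 0.781). The 3KR call was also lost in the top 50% of the list by score (7 of 24, odds ratio 3.12, Fisher's exact adjusted p = 0.0872) and with the shortened list (3 of 24, odds ratio 2.37, adjusted p = 0.394).

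At the 10 kb distance several groups that are not p53 pathways were called in 3KR alone. They were AP-1 and MAPK response genes (10 of 20, odds ratio 4.07, 1.69 to 9.78, Fisher's exact adjusted p = 0.0169), with Fosl2, Ier2 and Ier3, and housekeeping genes (10 of 20, odds ratio 4.07, 1.69 to 9.78, Fisher's exact adjusted p = 0.0169), with Psmb2, Sdha and Eef2. Epidermal differentiation genes followed (10 of 24, odds ratio 2.90, 1.29 to 6.54, Fisher's exact adjusted p = 0.0347), with Zfp750, a differentiation regulator, Krtdap and Ovol1. Genes of inflammation and antigen presentation were at 9 of 20 (odds ratio 3.33, 1.38 to 8.03, Fisher's exact adjusted p = 0.0330). In WT the same groups gave 2 of 20 (Ier2 and Junb, adjusted p = 0.294), 1 of 20 (Ppia, adjusted p = 0.692), 1 of 24 (Ovol1, adjusted p = 0.753) and 0 of 20 (adjusted p = 1), all by Fisher's exact test. Of 7 alternatives, 2 ended the 3KR call for AP-1 genes (odds ratio 2.80 and 2.93), 3 for housekeeping genes (2.52 to 3.03), 5 for differentiation genes (1.51 to 2.36) and 4 for inflammation genes (0.404 to 2.80). In WT, AP-1 genes were called at 50 kb (7 of 20, odds ratio 4.31, Fisher's exact adjusted p = 0.0144) and by nearest gene (7 of 20, 8.82, adjusted p = 3.8e-04), and so were differentiation genes (9 of 24, 4.80, adjusted p = 0.00426, and 7 of 24, 6.74, adjusted p = 0.00123, Fisher's exact tests). Chromatin regulators were not called (0 of 22 in WT and 5 of 22 in 3KR, with Kdm6b and Smarca4, Fisher's exact adjusted p = 1 and 0.669).

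At the 10 kb distance markers of other skin cell types were not called in either list. Dermal fibroblast markers had a summit at 0 of 12 genes in WT and 3 of 12 in 3KR (Fisher's exact adjusted p = 1 and 0.669), melanocyte markers at 0 and 1 of 10 (adjusted p = 1 and 1), and immune cell markers at 0 of 15 in both (adjusted p = 1 and 1). Endothelial markers had 1 of 11 in WT, Eng, and 0 in 3KR (Fisher's exact adjusted p = 0.543 and 1). Hair follicle markers had 1 of 12 in each, Lhx2 in WT and Lrig1, named after its value was seen, in 3KR (Fisher's exact adjusted p = 0.557 and 1). Under other distances, fibroblast markers were called in 3KR by nearest gene (7 of 12, odds ratio 5.32, Fisher's exact adjusted p = 0.0112) and hair follicle markers in WT at 50 kb (5 of 12, odds ratio 5.71, adjusted p = 0.0191).

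**Figure D4:**
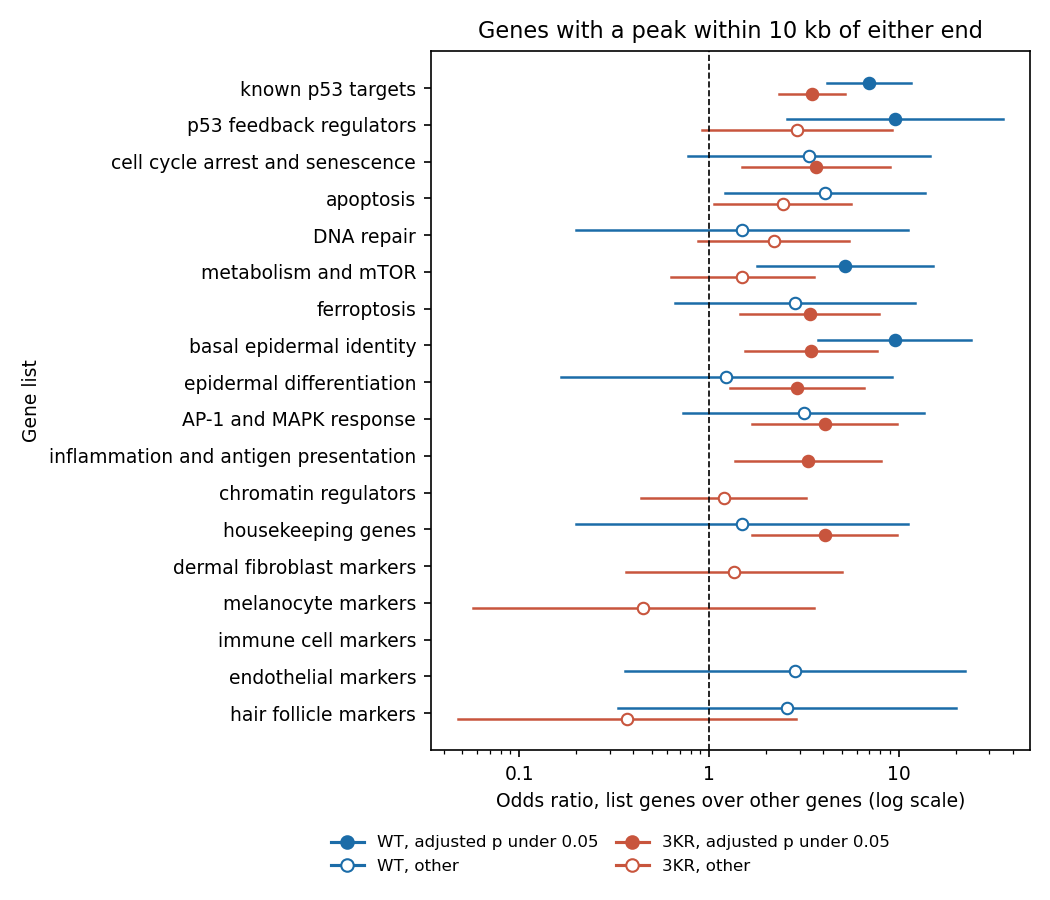
Odds ratio of having a summit within 10 kb of either gene end for 18 gene lists (vertical axis) against other protein-coding genes, on a log scale (horizontal axis), WT in blue and 3KR in red, with 95% intervals as lines and filled points for an adjusted p under 0.05. Lists with no gene beside a summit have no point. Known p53 targets stand at 6.98 in WT and 3.47 in 3KR.

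Whether a group differed between genotypes was tested among genes with a summit in exactly 1 list. None of the 18 lists passed in a 2-sided Fisher's exact test (lowest adjusted p = 0.734), and 1 list, the endothelial markers, had an unadjusted exact p under 0.05. For known targets the odds ratio of 3KR-only over WT-only genes was 0.446 (0.135 to 1.48, Fisher's exact adjusted p = 0.734). Thus a list called in 1 genotype alone was not shown to differ from the other genotype. The test could hardly detect an excess on the 3KR side, since 3755 genes had a summit in 3KR only and 175 in WT only. Housekeeping genes, with 9 in 3KR only and 0 in WT only, could lie no further to that side and did not pass. For lists called in 3KR alone the test therefore cannot decide whether the genotypes differ. Within 1 kb of gene ends, 20 known targets had a summit only in 3KR, 5 only in WT and 7 in both. Targets were thus more numerous in 3KR, yet they made up 0.930% of 3KR-only genes and 9.43% of WT-only genes, since other genes counted 2131 and 48 (odds ratio 0.0901, 0.0325 to 0.250, Fisher's exact adjusted p = 0.0022). Apoptosis genes (2 in 3KR only, 3 in WT only, odds ratio 0.0155, Fisher's exact adjusted p = 0.0022) and feedback regulators (3 and 2, odds ratio 0.0356, Fisher's exact adjusted p = 0.0325) also passed at 1 kb, on the same 5 WT-only genes, Bbc3, Perp and Phlda3 for apoptosis and Ccng1 and Mdm2 for feedback. Of these 5, Mdm2, Perp and Phlda3 had a 3KR summit within 10 kb, as did 15 of all 53 genes that were WT-only at 1 kb. With the 3KR list shortened to the WT length, known targets alone passed, with 3 genes in 3KR only and 11 in WT only (odds ratio 0.121, 0.0337 to 0.438, Fisher's exact adjusted p = 0.0063). Of those 11, 8 had a 3KR summit in the full list and became WT-only through the shortening, as did 243 of all 418 WT-only genes, so this value does not show targets that 3KR p53 left unbound. At 50 kb the odds ratio was 1.12 (Fisher's exact adjusted p = 1).

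Counted by site, 14 of 859 shared regions (1.63%, 0.973 to 2.72) lay within 10 kb of an end of a known target. The counts were 8 of 776 WT-only regions (1.03%, 0.523 to 2.02) and 44 of 5828 3KR-only regions (0.755%, 0.563 to 1.01). Shared regions exceeded 3KR-only regions (odds ratio 2.18, 1.19 to 3.99, 2-sided Fisher's exact adjusted p = 0.0490). Shared and WT-only regions were not told apart (1.59, 0.664 to 3.81, Fisher's exact adjusted p = 0.391), nor were 3KR-only and WT-only regions (0.730, 0.343 to 1.56, Fisher's exact adjusted p = 0.391).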

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

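The tests of explanations in this part were all chosen after the results were seen. The comparison of location itself was planned before the data were examined, but for transcription start sites, which gene ends replaced. The odds of lying at a gene end were 6.17 times higher for 3KR-only than for WT-only regions, a difference between classes of regions that passed its own test. That test counted regions of combined lists without replicates, so it cannot assign the difference to genotype. Summits outside the assembled chromosomes, which the comparisons of location and genes left out, were flagged above a cutoff of 3, with no expected number computed. There were 29 WT and 62 3KR summits on unplaced sequences, and 24 merged sites of each were shared. On mitochondrial sequence there were 6 3KR summits.

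The first pattern is the length of the 3KR list, 4.05 times that of WT. A WT list that is only a shorter copy of the 3KR list would have nearly all its regions in the longer one, and 53.03% (50.6 to 55.4) were there. That all WT-only regions were spread by chance over the genome is also argued against. Of 776, 8 lay within 10 kb of an end of a known p53 target, against a mean of 1.07 and at most 6 in 1000 random placements. With only 8 such regions, it stays open whether many of the other WT-only regions were chance calls. Random placement does not allow for background signal near genes, and WT-only regions lay at gene ends 2.22 times as often as it gives. The excess therefore does not show that the 8 regions are p53 sites. A difference in depth, enrichment or peak calling run that went along with genotype cannot be told apart from an effect of 3KR p53, because the lists have 0 columns of single libraries, and neither can a compound given to 3KR cells only, if Doxo in the 3KR run label names one, because 0 3KR summits lack that label. An effect of the genotype itself therefore stays open and untested.

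The second pattern is the position of 3KR-only regions at gene ends. A longer list that reaches weaker sites at gene ends is argued against as the whole cause, since with the 3KR list shortened to the WT length the odds ratio was 5.42 (4.30 to 6.85, 36.2% against 9.49%). Housekeeping genes had a 3KR-only summit within 1 kb of an end in 8 of 20 cases (40.0%, against 9.85% of other genes, odds ratio 6.10, 2.49 to 14.9), and known p53 targets in 22 of 98 (odds ratio 2.66, 1.65 to 4.28). DNA repair genes (odds ratio 3.92, 1.505 to 10.2), AP-1 genes and inflammation genes (both 3.05, 1.11 to 8.39) also had intervals above 1, while those of the other lists included 1, among them genes of basal epidermal identity, a condition added after the housekeeping value was seen (2 of 24, 8.33% against 9.88%, odds ratio 0.830, 0.195 to 3.53), and fibroblast, immune cell and endothelial markers (0 of 12, 0 of 15 and 0 of 11, upper bounds 6.16, 4.92 and 6.73). The expectation for signal at the ends of active genes in general, p53 targets or not, at first named housekeeping genes only. Their value met it. With basal epidermal genes required as well, a rule changed after that value was seen, the outcome was undecided. Such signal is therefore a candidate explanation, neither shown nor excluded. A compound given to 3KR cells only stays open because 0 3KR-only regions lack the Doxo label, and a biological difference between genotypes remains open.

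The third pattern is that the highest scored WT sites were often intergenic, at 64.2% in the highest decile against 48.9% of all WT regions. The 3KR decile gave 36.3% against 36.8%. On assembled chromosomes that decile held 159 regions in WT and 664 in 3KR, so it reached further down the 3KR list. The contrast therefore does not show a difference between genotypes. Of the 10 highest scored regions, 1 lay inside a gene in each list. Signal at chromosome ends is a candidate explanation for part of the WT pattern. In WT, 20 of 159 regions of the highest score decile lay outside the range of annotated genes of their chromosome, against 25 of 1476 other regions (odds ratio 8.35, 4.52 to 15.4). In 3KR these were 20 of 664 against 19 of 6020 (odds ratio 9.81, 5.21 to 18.5). The regions of the highest score decile beyond that range were on 16 chromosomes in each list. Of these 159 WT regions, 0 lay within 10 kb of an end of a known p53 target, which allows up to 1.89%. The listed targets therefore do not account for these sites. Only 22 of the 1476 other WT regions lay beside one, so most of the decile could not have done so in any case. The count cannot speak to p53 sites farther away or beside genes not listed. Repeats, reads with several matches and p53 motifs were not tested, as no genome sequence was used here.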

How the results depend on the processing

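No paired analysis was possible because the peak lists hold no values of single libraries, although the titles number the libraries 1 to 3 in each genotype, and for the same reason no replicate could be left out. Alternatives without the highest score decile, inside gene bodies, with shared summits only, and with the shortened 3KR list for location were chosen after seeing the data. The motif alternatives were not run, since no genome sequence was used here, and 50% coverage and 50% reciprocal overlap are the same rule for equal windows. Under 10 alternatives the overlap stayed above chance (1.08% to 60.5% of WT regions), and under 5 the gene-end odds ratio stayed above 1 (3.05 to 6.48). The score differences kept their direction with 50% overlap (4.72 in WT, 11.2 in 3KR). Known p53 targets were called in WT under all 7 alternatives (odds ratio 3.22 to 13.8).

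Where results moved, the cause was not tested beyond the shorter lists or windows themselves. Lists called for 3KR went from 8 to 3 within 1 kb, 3 in the top 50% by score and 0 with the shortened list, where known targets had an odds ratio of 2.11 (over 7 alternatives, adjusted p from 6.3e-09 to 0.164, Fisher's exact tests). Lists called for WT went from 4 to 7 at 50 kb, 7 by nearest gene, 2 in the top 50% and 2 with shared summits only. Lists that passed the test of 3KR-only against WT-only genes went from 0 to 3 within 1 kb and 1 with the shortened list. The odds ratio of known targets for 3KR-only over WT-only genes, under 1 in the other settings, was 1.12 at 50 kb.

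Of 126 list values under alternatives in each genotype, 90 in WT and 85 in 3KR kept direction and side of the threshold. Odds ratios crossed 1 in 23 cases in WT and 10 in 3KR, all from lists not called in either setting except inflammation genes in 3KR, called at first and 0.404 with the shortened list (0 of 20 genes). In 16 and 4 of these cases no gene of the list had a summit at first or under the alternative, so that the odds ratio rests on the 0.5 added to each cell. In 3KR, apoptosis genes stood at 0.764 within 1 kb and 0.338 with the shortened list, DNA repair genes at 0.839 in the top 50% and 0.873 with the shortened list, fibroblast markers at 0.336 within 1 kb and 0.687 in the top 50%, hair follicle markers at 1.42 at 50 kb and 1.27 by nearest gene, and endothelial markers at 1.42 by nearest gene. In WT, within 1 kb, in that order chromatin regulators, immune cell markers and inflammation genes stood at 2.09, 3.03 and 2.29, and in the top 50% at 1.29, 1.87 and 1.42. Chromatin regulators were at 1.26 at 50 kb, and with shared summits only immune cell markers were at 1.41, inflammation genes at 1.07 and ferroptosis genes at 0.972. At 50 kb, by nearest gene and with gene bodies, DNA repair and housekeeping genes both stood at 0.887, 0.858 and 0.992, fibroblast markers at 0.319, 0.651 and 0.753, and melanocyte markers at 0.887, 0.776 and 0.896. Differentiation genes were at 0.819 with gene bodies.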

Other observations

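The sites in this part were chosen after their values were seen, since they lie inside long genes and farther than 10 kb from either end. Trp63, the gene of the p53 relative p63 that maintains the basal layer (chromosome 16, 25683763 to 25892088), held 3 WT and 2 3KR summits inside it. The highest were at 25843859 in WT, rank 68 of 1667, and at 25843852 in 3KR, rank 43 of 6752, and a lower pair at 25835890 and 25835885 was also shared. Sesn1, a stress-induced regulator of mTOR signalling, had shared summits at 41881651 and 41881613 on chromosome 10. Mdm4, the gene of an MDM2 partner that inhibits p53, had them at 133019596 and 133019590 on chromosome 1. The basement membrane gene Lama3 had them at 12359252 and 12359264 on chromosome 18, and the hemidesmosome gene Dst at 34160105 and 34160111 on chromosome 1. With gene bodies included, the odds ratio of basal epidermal identity genes was 16.1 in WT (Fisher's exact adjusted p = 1.5e-07) and 9.87 in 3KR (Fisher's exact adjusted p = 1.1e-06), though long genes then have more room for a summit. Over 7 alternatives these adjusted p-values ran from 1.8e-10 to 0.113 in WT and from 1.8e-09 to 0.781 in 3KR, in Fisher's exact tests.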
